A study of Homo sapiens with 12 samples.

How the data were processed

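RNA of HMC-1 cells was measured in 12 samples, 2 in each of 6 groups, on Affymetrix arrays with 22277 probe sets. Biotin-labelled cRNA was prepared from 8 ug of total RNA, per the labels' protocols. The authors deposited 1 table of log2 expression values with 1 column per array, and the values were made with GCRMA, per the submitters' processing notes. GCRMA corrects the background by probe sequence, normalizes the arrays to a common distribution and summarises the probes of a set on the log2 scale, so overall differences in RNA amount are removed and values near the floor are compressed. The GCRMA version and the array's genome build were not given in the sources used here, and no coordinates are used.

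The 62 control probe sets were left out. Probe sets with a log2 value above 4 on at least 2 arrays were tested, which left 14817. The platform annotation gave 1 gene symbol for 19070 probe sets and several for 1043, counted without leaving out control probe sets. Of the 22215 probe sets other than controls, 2108 had none. Symbols were updated through gene identifiers in the RefSeq gene table of assembly GRCh38.p14, which matched 19058 of the 19070, and only probe sets with 1 symbol were named. For each gene the tested probe set with the highest mean stood for the gene, giving 8656 genes. Probe sets whose names end in _x_at can also bind related transcripts.

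Groups were compared with limma 3.58.1 in R 4.3.3, in 1 model with a mean per group over all 12 arrays (6 residual degrees of freedom), moderated by empirical Bayes, with two-sided tests. Adjusted p-values are Benjamini-Hochberg values within each comparison, and the threshold was 0.05. The comparisons were each activation against untreated, T cell membranes against A3, the peptide against none in each background, and the interaction of the peptide with each activation. A gene at or below the limit of 4 on both arrays of a group has only a bound: the change is given as at least the brighter group's mean minus the limit. Values are log2 means ± SD (n = 2) unless SE is named.

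Before the data were examined, 25 gene lists were fixed from general knowledge, as were the alternatives and the rule for named genes, and 24 lists had at least 5 measured genes. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it. No list was called with an estimated correlation in any of the 5 comparisons with untreated or of the peptide, nor in either interaction, while fry's directional test called 10 lists for A3, 14 for Tmem, 1 for ALL1, 2 for ALL1_A3 against A3 and 0 for ALL1_Tmem against Tmem. The named genes were the 10 largest rises and 10 largest falls that passed with no overlap between the arrays of the groups, up to 4 members per list with the smallest p, the 5 smallest p of each interaction, and ADORA3, GNAI2 and GNAI3, while GNAI1 had no tested probe set. Values of such a gene in another comparison are given as context.

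The share of the A3 or Tmem response kept with the peptide was the ratio of median changes over the called probe sets, beside 100 simulations without an effect of the peptide, taken over the called probe sets and over as many as were called in the data. The same number of simulations gave the correlation expected from shared arrays. Noise was drawn independently for each probe set, without shifts shared by many probe sets and with the same spread in all groups. The SD between replicates was 0.217 in untreated and 0.203 in ALL1_A3, against 0.115 to 0.157 in the others. Recovery in comparisons with those 2 groups may therefore be overstated. On simulated data, 94% of probe sets changed by 1 log2 unit and 40% of those changed by 0.5 were recovered for A3 against untreated, 100% and 42% for ALL1_A3 against A3, and 84% and 6% for the interaction of ALL1 with Tmem. Alternatives were no filter or a filter at 6, a trended and robust prior, only the groups of a comparison in the fit, a replicate block, a further quantile normalization, centring, array weights, 1 probe set per gene, a 2-fold threshold and leaving out each array. Pairs of untreated and ALL1_A3 arrays were also left out, and the list tests of the interactions were repeated without each array, which was chosen after seeing the data. Principal components, mixing fractions and figures used R, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.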

Results

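Gene expression was measured on 12 Affymetrix arrays in HMC-1, an established human mast cell line that grows in suspension. The 6 groups held 2 arrays each. One group was untreated and one received ALL1, a peptide whose target is not given in the sources used here. The A3 group was activated for 3 h through the adenosine A3 receptor, a Gi-coupled receptor, with the agonist Cl-IB-MECA. The Tmem group was incubated for 3 h with membranes of activated T cells. The ALL1_A3 and ALL1_Tmem groups received ALL1 for 1 h before the same activation. The design asked how each route of activation changes the transcripts of these cells and how the peptide changes each response. The median log2 value per array lay between 5.07 and 5.18, and 62.4% to 64.1% of the probe sets lay above a log2 value of 4. The number of arrays limited the precision, and because the labels do not say that the replicates came from separate cultures, p-values measure only the spread between these samples.

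Principal component 1 held 75.6% of the variance and set the 4 arrays with T cell membranes apart from the other 8, and component 2 held 11.9%. Replicates correlated across probe sets at r = 0.997 in ALL1, 0.994 in A3, 0.996 in Tmem and 0.996 in ALL1_Tmem, but at 0.989 in untreated and 0.990 in ALL1_A3. In those last groups 169 and 153 probe sets differed more than 2-fold between replicates, against at most 17 in the others. On an axis running from the mean of ALL1 at 0 to the mean of A3 at 1, the untreated arrays lay at 0.625 and 0.186 and the ALL1_A3 arrays at 0.699 and 0.261. The median of the 42 measured interferon response genes, relative to the mean of the 12 arrays, was 0.36 log2 units on untreated replicate 1 and -0.69 on replicate 2. On ALL1_A3 replicates 1 and 2 it was 0.33 and -0.75. It lay between -0.72 and -0.62 on the ALL1 arrays and between 0.24 and 0.39 on the arrays of A3, Tmem and ALL1_Tmem.

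**Figure D1:**
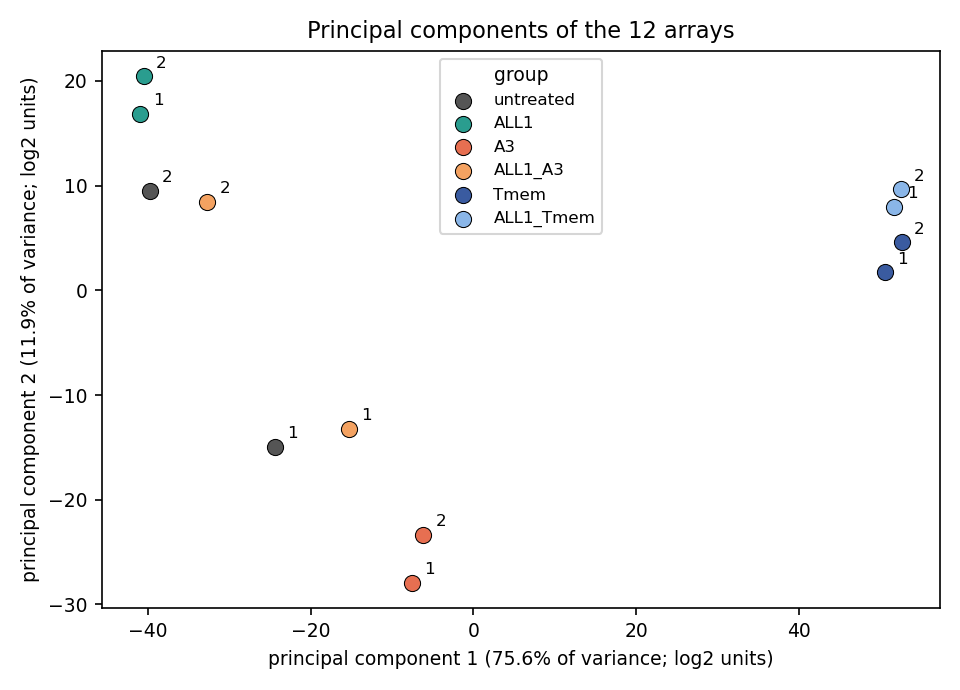
Each point is 1 array, placed by its scores on principal components 1 and 2 (log2 units) of the tested probe sets, coloured by group and numbered by replicate. Component 1, with 75.6% of the variance, separates the 4 arrays with T cell membranes, and the replicates of untreated and of ALL1_A3 lie farther apart than those of the other groups.

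**Figure D2:**
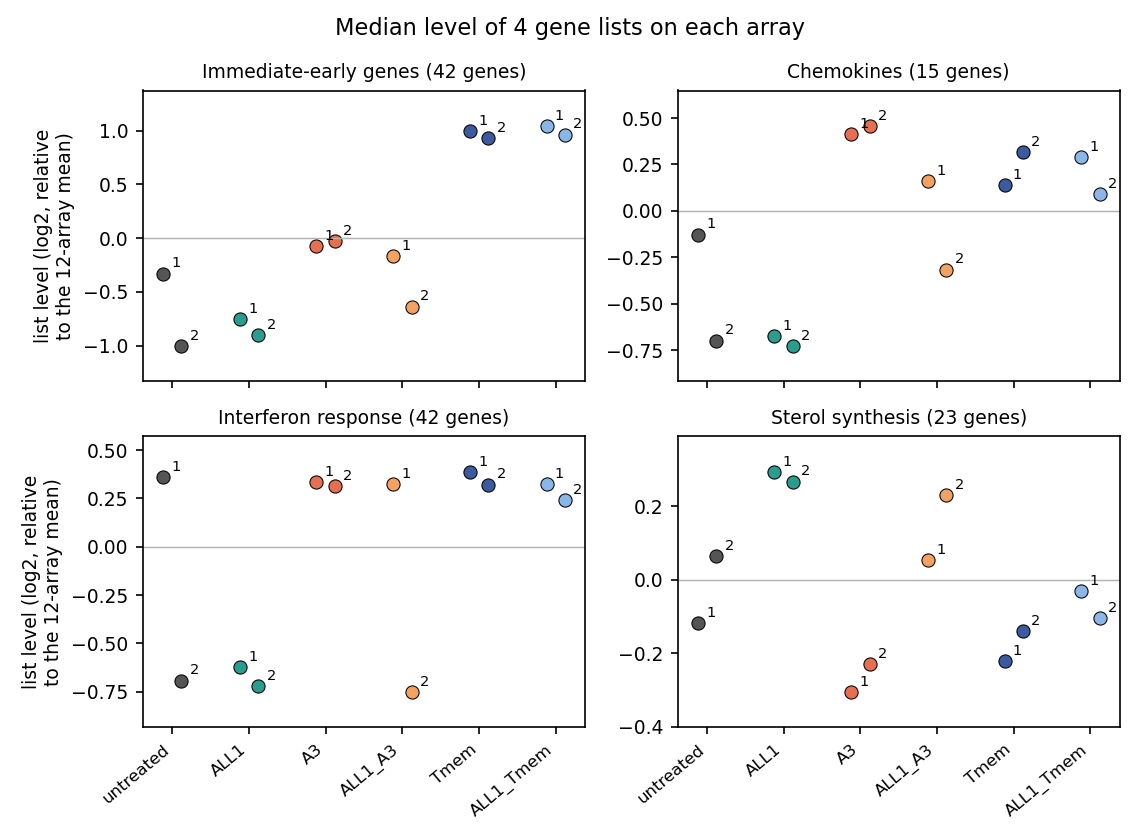
Points show the median log2 level of the measured genes of 4 lists on each array, relative to each gene's mean over the 12 arrays, with the replicate number beside each point. The interferon response list lies between -0.75 and -0.62 on 4 arrays and between 0.24 and 0.39 on the other 8, and the sterol synthesis list is at 0.29 and 0.27 on the ALL1 arrays.

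Activation through the A3 receptor raised transcripts of secreted signals and early-response genes. RGCC, a regulator of the cell cycle, rose from 4.70 ± 1.89 to 9.41 ± 0.12 (mean log2 value ± SD, n = 2), a change of 4.71 log2 units with a standard error of 0.70 (adjusted p = 0.0129). IL3, which encodes a growth factor for mast cells, rose by 3.95 ± 0.63 log2 units (SE, adjusted p = 0.0166). INHBA, which encodes a subunit of activin A, rose by 3.90, and CCL4, a chemokine, rose by 3.47 ± 0.72 (adjusted p = 0.0387). CRTAM, RRAD, CD24, SPP1 and EGR3 rose by 3.74, 2.91, 2.79, 2.66 and 2.66 log2 units. Without untreated replicate 2, CCL4, SPP1 and EGR3 differed by 2.27, 1.77 and 1.65 (adjusted p = 0.160, 0.214 and 0.211). NPTX2 rose from 3.01 ± 0.41, not above the limit of detection, to 6.00 ± 0.10, at least 2.00 log2 units. The decreases were smaller. CD2, an adhesion molecule, fell by 1.13, IL7 fell by 1.00, SULT2A1 fell by 0.97, and SIGLEC8, an inhibitory receptor of mast cells and eosinophils, fell by 0.77. ADORA3, the gene of the A3 receptor, fell by 0.73 log2 units (SD 0.21 in untreated and 0.037 in A3, adjusted p = 0.0186). The Gi subunit genes GNAI2 and GNAI3 differed by -0.09 and 0.12 (adjusted p = 0.798 and 0.598).

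Among the gene lists, 8 of 41 NF-kB targets rose and 33 did not pass, among them REL by 1.44 and NINJ1 by 1.49, with 21 higher and 2 lower when adjusted over the list alone. Of 27 cytokines and growth factors, 8 rose and none fell, among them ADM, which encodes adrenomedullin, by 2.14 and VEGFA by 1.10. Adjusted over the list alone, 14 rose and 2 fell. Of 15 chemokines, 5 rose and 10 did not pass, with CCL7 up by 2.44, CCL5 by 1.63 (1.08 without untreated replicate 2) and CCL1 by 1.60, and 10 rose when adjusted over the list alone. CXCL3 rose from 3.64 ± 0.17, below the limit, to 5.55 ± 0.25, at least 1.55 log2 units. Of 42 immediate-early genes, 5 rose, including SIK1 by 1.50, GADD45A by 1.81 and MYC by 0.75, and 23 rose adjusted over the list alone. Of 26 genes downstream of ERK signalling, 6 rose, including the phosphatase gene DUSP5 by 1.21, and PLAT fell by 0.58; adjusted over the list alone, 11 rose and 2 fell. Of 19 members of the TNF and TNF receptor families, 5 rose, including TNFRSF21 by 1.09 and TNFRSF1B by 1.07, and 8 rose adjusted over the list alone. Of 20 cAMP and CREB genes 2 rose, and 10 rose adjusted over the list alone. With the preset correlation, camera called these lists higher. With an estimated correlation the adjusted p was 0.163 for NF-kB targets, 0.123 for cytokines, 0.123 for chemokines, 0.199 for immediate-early genes, 0.123 for ERK genes, 0.123 for the TNF families and 0.234 for cAMP and CREB genes.

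The remaining lists that camera called moved with few members past the test. Of 34 ER stress genes 3 rose, including XBP1 by 0.68 and DDIT4 by 0.95, and 4 rose adjusted over the list alone. Of 33 hypoxia and glycolysis genes 4 rose, among them the glucose transporter gene SLC2A1 by 0.98, and 6 rose adjusted over the list alone. Of 25 antigen presentation genes 1 rose, HLA-DQB1 by 0.61, as when adjusted over the list alone. Of 46 cell cycle genes, called lower as a list, CCND1 rose and CENPA fell by 0.59, and 11 fell and 1 rose adjusted over the list alone. The sterol synthesis list (23 genes, median -0.25) was called lower with no member past the test, and adjusted over the list alone 1 rose and 4 fell. Of 15 adenosine and purine genes ADORA3 alone fell, and 3 fell adjusted over the list alone. The interferon response list was called higher with a median of 0.48, but none of its 42 genes passed, also when adjusted over the list alone, and GBP2 differed by 1.79 (adjusted p = 0.198). Untreated replicate 1 lay at the level of A3 for this list and replicate 2 did not. With an estimated correlation the adjusted p was 0.199 for ER stress, 0.199 for hypoxia, 0.352 for antigen presentation, 0.234 for cell cycle, 0.234 for sterol synthesis, 0.123 for adenosine and 0.502 for interferon response.

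In total 409 of 14817 probe sets differed between A3 and untreated, 293 higher and 116 lower, which covered 257 of 8656 genes. Of the 119 that changed at least 2-fold, 118 were higher. The count depended on single arrays, with 914 without untreated replicate 1 and 44 without untreated replicate 2, 0 in limma without either A3 array (2130 and 2489 at unadjusted p under 0.05, for replicates 1 and 2), 179 without either ALL1 array, 624 without either ALL1_A3 array, 155 without either Tmem array and 163 without either ALL1_Tmem array. With only the 4 arrays of the comparison in the fit it was 29, and with array weights 165.

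**Figure D3:**
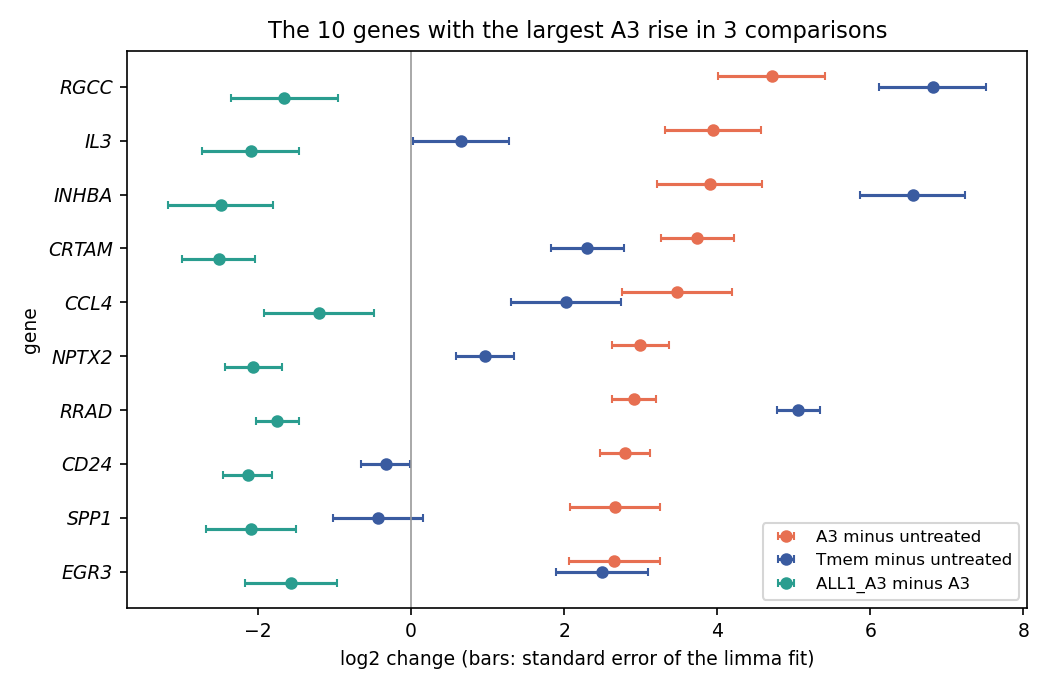
Points show the log2 change and bars the standard error from limma for the 10 genes with the largest called rise in A3 against untreated, in A3 minus untreated, Tmem minus untreated and ALL1_A3 minus A3. RGCC changed by 4.71 with A3 and 6.82 with T cell membranes, and CD24 by 2.79 with A3 and -2.14 with the peptide before A3.

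T cell membranes changed far more of the measured transcripts than A3. LPAR6, a receptor for lysophosphatidic acid, rose from 2.54 ± 0.024 to 10.05 ± 0.069, at least 6.05 log2 units. The matrix metalloproteinase genes MMP10 and MMP1 rose from 3.40 ± 0.096 and 2.36 ± 0.31 to 10.37 ± 0.041 and 8.41 ± 0.15, at least 6.37 and 4.41 log2 units. CXCL3 rose from 3.64 ± 0.17 to 10.53 ± 0.089, at least 6.53. DCSTAMP rose from 3.66 ± 0.19 to 10.27 ± 0.060, at least 6.27, and MAL rose from 3.81 ± 0.16 by at least 6.00. RGCC rose by 6.82 ± 0.70 (SE, adjusted p = 4.811e-05), INHBA by 6.56, INSM1 by 5.85 and CXCL8, the neutrophil chemokine interleukin-8, by 5.52 (3.62 without untreated replicate 2). Among the decreases, ITPKB fell by 2.96, FZD2 fell by 2.79, the calcium channel gene ORAI3 fell by 2.63, SLA fell by 2.60 and MYB, a transcription factor of blood progenitors, fell by 2.58. PSRC1 fell from 6.34 ± 0.45 to 3.22 ± 0.062, at least 2.34 log2 units. ADORA3 fell by 1.50 (adjusted p = 1.033e-05), GNAI3 rose by 0.46, and GNAI2 differed by -0.26 (adjusted p = 0.233).

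Of the 42 immediate-early genes, 34 rose, 2 fell and 6 did not pass, with ARC up by 5.30, DUSP1 by 4.18 and EGR1 by 3.06, and the counts adjusted over the list alone were again 34 and 2. Of 26 ERK genes 18 rose and 3 fell, with DUSP5 up by 2.97 and the cyclin gene CCND1 up from 3.91 ± 0.065 to 7.79 ± 0.045, at least 3.79; adjusted over the list alone, 18 rose and 4 fell. Of 27 cytokines and growth factors 16 rose and 1 fell, and adjusted over the list alone also 16 and 1. IL1B rose by 3.42, ADM by 3.62, and IL1A from 2.87 ± 0.088 to 6.93 ± 0.17, at least 2.93. Of 41 NF-kB targets 22 rose and 5 fell, the latter including TNIP1 by 1.25, with 23 and 6 adjusted over the list alone. Of 15 chemokines 7 rose and none fell, as when adjusted over the list alone, with CCL7 up by 4.99. Of 19 TNF family members 9 rose and 1 fell, also adjusted over the list alone, with TNFRSF1A up by 1.64. Of 20 cAMP and CREB genes 11 rose and 2 fell, with NR4A1 up by 1.34, and 12 rose and 4 fell adjusted over the list alone. Of 31 adhesion and matrix protease genes 11 rose and 6 fell, also adjusted over the list alone. Of 34 ER stress genes 14 rose and 3 fell, with SLC7A11, a cystine transporter gene, up by 3.35 and XBP1 by 1.25, and 16 and 3 adjusted over the list alone. Of 46 cell cycle genes 33 fell and 4 rose, with KIF20A, a mitotic kinesin gene, down by a change of -2.42 and the checkpoint kinase gene BUB1B by -1.22; adjusted over the list alone, 35 fell and 4 rose.

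The 42 interferon response genes were called higher with a median of 0.44, and 5 rose, among them MX2 by 2.14, and PSMB8 fell by 0.34, while none passed adjusted over the list alone. Their level on untreated replicate 1 was that of the Tmem arrays, and without untreated replicate 2 MX2 differed by 1.09 (adjusted p = 0.250). With an estimated correlation the adjusted p was 0.293 for immediate-early genes, 0.136 for ERK genes, cytokines, TNF families and adhesion, 0.326 for NF-kB targets and chemokines, 0.555 for cAMP and CREB genes, 0.289 for ER stress, 0.416 for cell cycle and 0.680 for interferon response. Of 22 mast cell lineage genes 9 fell and 3 rose, and adjusted over the list alone 10 fell and 3 rose, while camera did not call the list (adjusted p = 0.432). KIT, the stem cell factor receptor gene, fell by 0.70 ± 0.074 (SE), GATA1 fell by 1.17, TAL1 fell by 0.64, and GATA2 rose by 0.93. Of 14 T cell markers above the limit, 4 rose and 2 fell, also adjusted over the list alone, without a call for the list (adjusted p = 0.0556). IL7R rose by 3.68, GATA3 by 1.67 and TRBC1, the T cell receptor beta constant gene, from 3.18 to 5.31, at least 1.31, while CD2 fell by 1.70.

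In total 6367 probe sets (43.0%) differed between Tmem and untreated, 2455 higher and 3912 lower, in 3879 genes, and 1458 changed at least 2-fold. After each array was centred on its median, 48.6% of the called probe sets were higher, against 38.6% as deposited. In 26 genes called probe sets of the same gene moved in opposite directions. The count lay between 4724 and 6491 when any 1 of the 12 arrays was left out.

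The direct comparison of the activators, Tmem against A3, found LPAR6 higher with T cell membranes by at least 6.05 log2 units, from 3.15 ± 0.15 to 10.05 ± 0.069, CXCL3 by 4.98, MMP10 by 4.67, INSM1 by 4.63, MAL by 4.48 and ARC by 4.32. RCAN1, an inhibitor of calcineurin, was lower by a change of -3.55 (adjusted p = 0.00122), IL3 by -3.30 (adjusted p = 0.00326), SPP1 by -3.10, NEDD9 by -2.95 and ITPKB by -2.91. CD24 was lower in Tmem (3.44 ± 0.33) than in A3 (6.57 ± 0.17) by at least 2.57. Of 42 immediate-early genes 24 were higher and 3 lower, with 28 and 4 adjusted over the list alone. Of 26 ERK genes 16 were higher and 3 lower (17 and 3 adjusted over the list alone), of 27 cytokines 13 and 1 (13 and 3 adjusted over the list alone), and of 46 cell cycle genes 4 and 20 (4 and 26 adjusted over the list alone). The chemokine CCL5 was lower by a change of -1.63 and CCL7 higher by 2.55. With an estimated correlation the adjusted p was 0.621 for immediate-early genes, 0.231 for ERK genes, 0.492 for cytokines and 0.747 for cell cycle genes. In total 4339 probe sets differed, 1860 higher and 2479 lower, and 54.3% were higher after centring against 42.9% as deposited. Without Tmem replicate 2 there were 2866.

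Among the 293 probe sets higher with A3, 230 were also higher with T cell membranes, where independent lists give 48.5, and among the 116 lower, 105 were lower with both, where independent lists give 30.6. The log2 changes of both comparisons correlated at r = 0.655 across probe sets, which are not independent replicates. Unchanged groups set against the same untreated arrays gave a simulated r of 0.498 and no more than 1 shared call, and the covariance was 0.146 against a simulated 0.0106. Both comparisons use the same 2 untreated arrays, which were not split between them, so part of the excess may come from these arrays. The 335 shared calls were 759 without untreated replicate 1, 31 without untreated replicate 2, 148 without either ALL1 array, 0 without either A3 array, 514 without either ALL1_A3 array, 126 and 127 without Tmem replicates 1 and 2, and 134 without either ALL1_Tmem array.

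The peptide alone raised genes of sterol synthesis. MSMO1, a sterol methyl oxidase gene, rose from 9.12 ± 0.39 to 10.34 ± 0.087, by 1.22 ± 0.17 log2 units (SE, adjusted p = 0.0230). HMGCS1, the gene of HMG-CoA synthase, rose by 0.90 (adjusted p = 0.0173), HSD17B7 by 0.78 and SQLE, which encodes squalene epoxidase, by 0.46. These were the 4 of 23 sterol synthesis genes that passed, none fell, and 12 rose adjusted over the list alone. PHLDA2 rose by 0.89, JUND by 0.86, KIF21B by 0.79 and PLAT, tissue plasminogen activator, by 0.63. LBH fell by 2.03 ± 0.22 (SE, adjusted p = 0.00809), SERPINB1, an inhibitor of neutrophil proteases, fell by 1.66, SH2D2A fell by 1.38, SLA fell by 1.17 and the cholesterol exporter gene ABCA1 fell by 1.08. HRH4, the histamine H4 receptor gene, fell from 6.03 ± 0.023 to 4.91 ± 0.021 (adjusted p = 0.00729). ADORA3, GNAI2 and GNAI3 differed by 0.16, -0.05 and -0.02 (adjusted p = 0.643, 0.940 and 0.962).

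Camera called the sterol list higher (adjusted p = 0.391 with an estimated correlation) and the 46 cell cycle genes higher (0.641 with an estimated correlation). It called lower the 42 interferon response genes (adjusted p = 0.641 with an estimated correlation), the 15 chemokines (0.641), the 20 cAMP and CREB genes (0.685), 33 hypoxia genes (0.641) and 25 antigen presentation genes (0.641). No member of these other lists passed, and adjusted over the list alone 4 chemokines fell, 5 cAMP and CREB genes fell and 1 rose, and none of the rest passed. CCL4 differed by -2.85 (adjusted p = 0.135) and was at 10.18 and 7.77 on the untreated arrays, 6.25 and 6.01 with ALL1. The untreated arrays lay at 0.36 and -0.69 for the interferon list, -0.13 and -0.70 for the chemokine list, and -0.12 and 0.06 for the sterol list, which was at 0.29 and 0.27 on the ALL1 arrays. In total 55 probe sets changed, 24 higher and 31 lower, in 31 genes, and 1911 had an unadjusted p under 0.05. The count was 24 without untreated replicate 1, 337 without untreated replicate 2, 0 in limma without either ALL1 array (1420 and 1030 at unadjusted p under 0.05, for replicates 1 and 2), 30 without either A3 array, 144 without either ALL1_A3 array, 17 without either Tmem array and 27 without either ALL1_Tmem array. With only the 4 arrays of the comparison in the fit, limma called 0, with 1534 at unadjusted p under 0.05.

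The peptide before A3 activation raised 5 of 23 sterol synthesis genes, of which MSMO1, HMGCS1 and HSD17B7 had also risen with the peptide alone, and several genes that A3 had raised were lower. MSMO1 rose by 1.11, HMGCS1 by 1.05 ± 0.12 (SE, adjusted p = 0.00944), MVD by 0.92, SC5D by 0.94 and HSD17B7 by 0.64, and 18 sterol genes rose adjusted over the list alone. SQLE differed by 0.27 (adjusted p = 0.132). LMO2 rose by 0.88, KIF21B by 0.82, PLAT by 0.79 and the purine receptor gene P2RX1 by 0.62. CRTAM fell by 2.51 (adjusted p = 0.0475), IL24 fell by 2.19, CD24 fell by 2.14, NPTX2 fell by 2.06, CXCL3 fell by 1.93, RRAD fell by 1.75, GATA3 fell by 1.02 and MYC fell by 0.66. CGA, the common subunit of the glycoprotein hormones, fell from 6.98 ± 0.014 to 4.59 ± 0.30. Without ALL1_A3 replicate 2, CRTAM and NPTX2 differed by -1.53 and -1.34 (adjusted p = 0.0663 and 0.109). DKK2 fell from 4.89 ± 0.39 to 2.62 ± 0.31, at least 0.89 log2 units. HRH4 fell by 0.77 (adjusted p = 0.0164). IL3 differed by -2.10 (adjusted p = 0.149), and its ALL1_A3 replicates were at 7.13 and 4.64. ADORA3, GNAI2 and GNAI3 differed by 0.46, 0.18 and -0.10 (adjusted p = 0.103, 0.644 and 0.743).

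**Figure D4:**
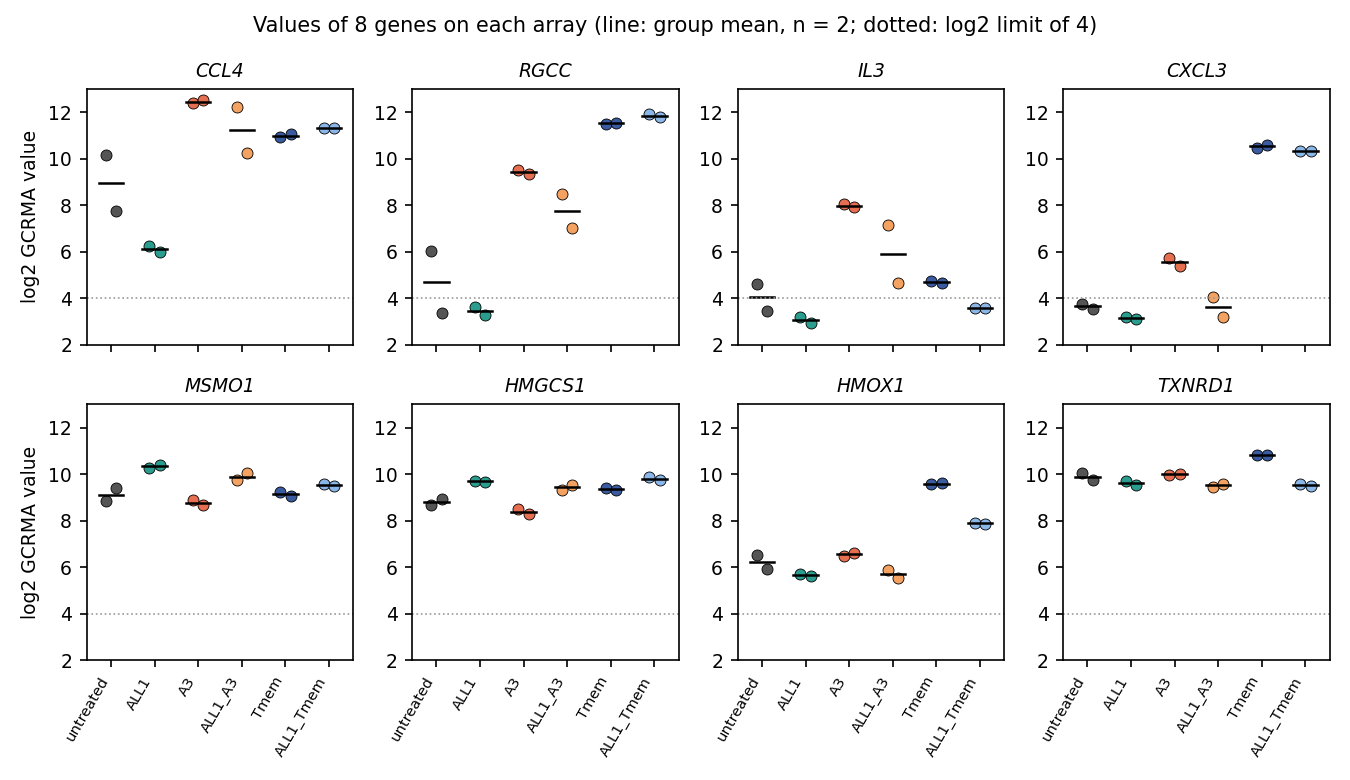
Points show log2 values of 8 genes on each array and lines the group means (n = 2), with the detection limit of 4 dotted. CCL4 was at 12.24 and 10.24 on the ALL1_A3 arrays and 10.18 and 7.77 on the untreated arrays, while HMOX1 was at 9.58 ± 0.030 in Tmem and 7.88 ± 0.018 in ALL1_Tmem.

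Camera called 13 lists in this comparison. The sterol list was higher (adjusted p = 0.166 with an estimated correlation), as were the 15 adenosine and purine genes (1 rose, 5 adjusted over the list alone, adjusted p = 0.166 with an estimated correlation) and the 46 cell cycle genes (CCND3 rose by 0.58, 1 adjusted over the list alone, adjusted p = 0.383 with an estimated correlation). Lower were 42 immediate-early genes (1 fell; adjusted over the list alone 11 fell and 2 rose), 15 chemokines (1 fell, 4 adjusted over the list alone), 41 NF-kB targets (3 fell, including NINJ1 and REL by 1.09 and 0.96; adjusted over the list alone 5 fell and 3 rose), 27 cytokines (1 fell; adjusted over the list alone 7 fell and 2 rose) and 19 TNF family members (TNFRSF1B fell by 1.03, 1 adjusted over the list alone). With an estimated correlation the adjusted p was 0.383, 0.210, 0.356, 0.303 and 0.190 in that order. Also lower, with no member past the test, were the interferon response, cAMP and CREB, hypoxia, antigen presentation and ER stress lists, with adjusted p = 0.404, 0.404, 0.356, 0.356 and 0.383 with an estimated correlation. Adjusted over the list alone, 7 cAMP and CREB genes fell and 1 rose, 2 hypoxia genes and 1 antigen presentation gene fell, and none passed in the others. The ALL1_A3 arrays lay at 0.33 and -0.75 for the interferon list, 0.16 and -0.32 for the chemokine list, -0.16 and -0.64 for the immediate-early list, and 0.05 and 0.23 for the sterol list. In total 130 probe sets changed, 58 higher and 72 lower, in 83 genes. The count was 505 without ALL1_A3 replicate 1, 6 without ALL1_A3 replicate 2, 0 in limma without either A3 array (1726 and 2151 at unadjusted p under 0.05, for replicates 1 and 2), 335 without either untreated array, 28 without either ALL1 array, 25 without either Tmem array and 32 without either ALL1_Tmem array. With only the 4 arrays of the comparison it was 1, with array weights 51, and with a trended, robust prior 278.

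The 409 probe sets called in A3 against untreated had a median absolute change of 0.731 there and a median of 0.346, in the same direction, in ALL1_A3 against ALL1, a ratio of 0.473. Simulated data in which ALL1 had no effect gave a mean ratio of 0.757, between 0.718 and 0.799, but called 811 to 1029 probe sets for A3. Over the 409 probe sets with the smallest p in each simulation the mean was 0.791, between 0.732 and 0.870. In ALL1_A3 against ALL1 itself 1 probe set passed in limma, against 813 to 1034 in the simulations. There 1697 had an unadjusted p under 0.05, where chance gives 741, so the single call does not mean that no response was left. The ratio was 0.632 from replicates numbered 1 and 0.298 from replicates numbered 2, and 0.735 without ALL1_A3 replicate 2 and 0.287 without ALL1_A3 replicate 1. The simulations drew noise independently for each probe set, so their ranges leave out such joint shifts between replicates. They therefore cannot exclude a ratio of 0.473 without an effect of the peptide. Of the probe sets higher with A3, 55 were lower in ALL1_A3 than in A3. Independent lists give 1.42, but the shared A3 arrays favour such opposite calls by construction, and their number was not simulated. The changes correlated at r = -0.804 against a simulated -0.499 from the shared A3 arrays. The test of the difference between the peptide's effect with and without A3 passed for 0 probe sets in limma, with 709 at an unadjusted p under 0.05 where chance gives 741. It passed for 2 without untreated replicate 1 and 7 without ALL1_A3 replicate 1. The smallest p was that of MAL, with an adjusted p of 0.203 and no size given because MAL was at or below the limit on the untreated and ALL1 arrays, followed by XBP1 with a difference of -0.77 (adjusted p = 0.390). The peptide's changes in untreated and in A3-activated cells, which share no array, correlated at r = 0.650 across probe sets, and 10 probe sets rose and 6 fell in both. Each of these comparisons holds a group whose replicates lay far apart. Using 1 untreated and 1 ALL1_A3 array at a time was chosen after seeing the data. The r was 0.753 with untreated replicate 1 and ALL1_A3 replicate 2, and between 0.293 and 0.426 with the other pairs. An exchange of the labels of those 2 arrays stays open, as described below. Exchanged labels would put the A3 response into both comparisons, so r cannot be read as a repeated effect of the peptide.

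With T cell membranes, the peptide lowered HMOX1, the gene of heme oxygenase-1, from 9.58 ± 0.030 to 7.88 ± 0.018, a change of -1.70 (adjusted p = 0.0106). TXNRD1, which encodes thioredoxin reductase, fell by 1.29 (adjusted p = 0.00878), and GCLM, a subunit of the rate-limiting enzyme of glutathione synthesis, fell by 0.75 (adjusted p = 0.0435). HMOX1, TXNRD1 and GCLM had risen with membranes by 3.37, 0.95 and 1.58 log2 units. IL1A, the gene of interleukin-1 alpha, fell by 1.10, RUNDC3B fell by 1.08, GSPT2 fell by 0.74, RIT1 fell by 0.66 and USP6NL fell by 0.64. EMP1, an epithelial membrane protein gene, rose from 6.11 ± 0.019 to 7.93 ± 0.10, by 1.82 ± 0.19 (SE, adjusted p = 0.0106), and OSR2 rose by 0.68. SOX2 rose from 3.31 ± 0.21, below the limit, to 4.04 ± 0.0099, at least 0.04 log2 units. ADORA3, GNAI2 and GNAI3 differed by -0.16, 0.05 and -0.02 (adjusted p = 0.656, 0.945 and 0.970).

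Camera called 6 lists, and no member of them passed over all probe sets. Higher were 14 T cell markers (adjusted p = 0.607 with an estimated correlation), 23 sterol genes with a median of 0.08 (0.687) and 42 immediate-early genes (0.840). On the ALL1_Tmem arrays 15 and 16 of 34 T cell markers lay above the limit, against 10 to 13 on the other arrays. Over all probe sets the share above the limit was also highest there, at 63.9% and 64.1% against 62.4% to 63.3%. Lower were 34 ER stress genes (adjusted p = 0.607 with an estimated correlation), 33 hypoxia genes (0.687) and 36 ribosome biogenesis genes (0.840). Adjusted over the list alone, 1 T cell marker rose, 2 immediate-early genes rose and 1 fell, 2 hypoxia genes and 1 ribosome biogenesis gene fell, and no sterol or ER stress gene passed. In total 18 probe sets changed, 7 higher and 11 lower, in 11 genes, with 1671 at an unadjusted p under 0.05. After centring 57.7% of the calls were higher, against 38.9% as deposited. The count was 6 without either ALL1 array, 8 without either A3 array and 0 in limma without either Tmem array (854 and 1501 at unadjusted p under 0.05, for replicates 1 and 2) or either ALL1_Tmem array (1363 and 872). It was 3 with only the 4 arrays of the comparison and 113 with array weights.

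The 6367 probe sets called in Tmem against untreated had a median absolute change of 0.614 there and 0.651 in ALL1_Tmem against ALL1, a ratio of 1.06 (1.05 from replicates numbered 1 and 1.08 from those numbered 2). Data simulated with no effect of ALL1 gave a mean of 0.973, between 0.956 and 0.996. This range also leaves out shifts shared by many probe sets. The directions differed, with medians of 0.74 and 0.67 log2 units for the called rises, without and with the peptide, and of -0.57 and -0.64 for the called falls. The changes in these comparisons, which share no array, correlated at r = 0.927 across probe sets. The test of the difference between the peptide's effect with and without membranes passed for 0 probe sets in limma, with 1677 at an unadjusted p under 0.05 where chance gives 741. It passed for 2 without untreated replicate 1 and 5 without untreated replicate 2. INHBE came closest, with a difference of -1.94 ± 0.23 (SE, adjusted p = 0.0968), and EMP1 had the same adjusted p, with no size given because it was at or below the limit on the untreated and ALL1 arrays. The peptide's changes with membranes correlated at r = 0.133 with those in untreated cells and 0.234 with those in A3-activated cells.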

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

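The interaction comparisons and the gene lists were planned, but the tests of the lists on the interactions were not among the planned results, leaving out arrays from them was chosen after they had been seen, and every test of an explanation in this part was chosen after its result had been seen.

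The peptide's effect differed between A3-activated and untreated cells for 7 gene lists, and between membrane-activated and untreated cells for 9, by camera with a preset correlation. None of these calls passed with an estimated correlation, where the smallest adjusted p was 0.254 for A3 and 0.677 for membranes. The following adjusted p-values are those with the preset correlation. It was lower with A3 for immediate-early genes (median difference -0.23, adjusted p = 3.450e-05), ERK genes (-0.16, adjusted p = 5.738e-04), NF-kB targets (-0.14, adjusted p = 5.738e-04), ER stress genes (-0.09, adjusted p = 5.738e-04), cytokines (-0.14, adjusted p = 6.711e-04) and the TNF families (-0.10, adjusted p = 0.00607). It was higher with A3 for adenosine and purine genes (0.19, adjusted p = 0.0215). With T cell membranes the effect was higher than in untreated cells for interferon response genes (0.46, adjusted p = 3.559e-05), T cell markers (0.30, adjusted p = 0.00235), cAMP and CREB genes (0.21, adjusted p = 0.00398), immediate-early genes (0.24, adjusted p = 0.00469), chemokines (0.31, adjusted p = 0.00670) and antigen presentation genes (0.14, adjusted p = 0.0152). It was lower with membranes for sterol synthesis (-0.28, adjusted p = 3.559e-05), cell cycle (-0.15, adjusted p = 0.00110) and ER stress genes (-0.16, adjusted p = 0.00268). Replicates stood apart here, with untreated replicates 1 and 2 at 0.36 and -0.69 for the interferon list, -0.13 and -0.70 for chemokines and -0.05 and -0.69 for cAMP and CREB genes. Without untreated replicate 1, 3 of the 9 calls with membranes passed again, those of sterol synthesis, ER stress and T cell markers, the interferon difference was 0.02 (adjusted p = 0.772), and that of immediate-early genes turned to -0.08 (adjusted p = 0.819). Without untreated replicate 2, 0 of the 7 calls with A3 passed in camera (smallest adjusted p = 0.238) and the immediate-early difference turned to 0.06 (adjusted p = 0.984), without ALL1_A3 replicate 2 there were 2 of 7, and without A3 replicate 2 there were 4 of 7.

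The replicates of untreated and of ALL1_A3 lay far apart, with 169 and 153 probe sets over 2-fold apart. A3 RNA in untreated replicate 1 would give 1 mixing fraction for all transcripts, but the median fraction was 29.2% outside the interferon list and 88.5% within it, 3.03 times as high, which argues against it for those genes. Outside the list 79.0% of 81 probe sets lay within 2-fold of the median, so a mixture stays open there. An exchange of the labels of untreated replicate 1 and ALL1_A3 replicate 2 stays open, as it lowered the squared replicate difference to 0.555 times over all probe sets and 0.0264 times over the interferon list, but left 50 and 40 probe sets over 2-fold apart against at most 17 in the other groups, with that of the sterol list 1.62 times as large (bootstrap interval 0.885 to 2.58). Cultures in 2 interferon states across the groups may be part of it. The 12 arrays took 2 levels separated by 5.97 times the range within a level, with untreated and ALL1_A3 each on both levels. This restates the pattern, and exchanged labels would give the same 2 levels, so it does not decide between these explanations. A difference between cultures that is biological was not tested.

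Many A3 changes were smaller versions of the membrane changes. Membrane-activated RNA in the A3 samples would leave few transcripts higher in A3 than in Tmem, but 58 of the 293 probe sets that rose with A3, or 19.8%, were lower in Tmem than in A3, which argues against it for these. Among the 230 that rose with both activators 0.870% were lower in Tmem, but their rise would need a median share of 40.9% of membrane-activated RNA, while transcripts brightest in Tmem allow about 7.18% on the A3 arrays, and double that share could give the rise of 12.6% of the 230, which argues against a mixture as the cause of the shared part. A smaller share stays open. The 233 probe sets bright in Tmem gave a median mixing fraction of 12.9%, above the 7.18% allowed, and 51.9% lay within 2-fold of it. Their fractions therefore do not speak for a smaller share. Common steps of both activations, which the design names as treatments, stay open and untested.

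Some T cell marker genes were higher on the membrane arrays than without membranes, and 15 and 16 of 34 markers lay above the limit on the ALL1_Tmem arrays against 10 to 13 on the other arrays. The lower quartile of all probe sets was also highest on the ALL1_Tmem arrays, at 3.31 and 3.34 against 3.19 to 3.27. The higher count may therefore not be particular to T cell markers, which was not tested. Of 21 markers at or below the limit on all 8 arrays without membranes, 2, or 9.52%, were higher in Tmem than in untreated, TRBC1 by at least 1.31 and BCL11B, which stayed below the limit at 3.56. In ALL1_Tmem 6 of the 21, or 28.6%, were higher than in ALL1, and CD3D and LCK were at 3.97 and 4.02, against 3.17 and 3.40 in Tmem. GZMB, IL7R and GATA3, at 5.43, 5.72 and 5.54 in untreated cells and 10.86, 9.40 and 7.22 in Tmem, were at 9.40, 7.12 and 6.57 with A3, where no membranes were added (adjusted p = 0.0564, 0.0197 and 0.00561 in limma, so GZMB did not pass). For the 21 markers as a set, carried-over T cell RNA and a change in the mast cells could not be told apart. Levels other than those of TRBC1 lay near or below the limit. TRBC1 was above it, at 5.31 in Tmem and 5.01 in ALL1_Tmem, but a single gene does not decide between them.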

How the results depend on the processing

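The fits without 1 untreated and 1 ALL1_A3 array together were chosen after seeing the data, and all other alternatives here were planned. Counts of probe sets called by limma are given below in the order A3, Tmem and ALL1 against untreated, ALL1_A3 against A3, ALL1_Tmem against Tmem and Tmem against A3, and stood at 409, 6367, 55, 130, 18 and 4339. Leaving out 1 array or such a pair gave 0 to 1882, 4724 to 6547, 0 to 1224, 0 to 1549, 0 to 29 and 2866 to 5127 (a lone array is assumed to vary like the other groups). The interactions of ALL1 with A3 and with Tmem, at 0 in limma (709 and 1677 at unadjusted p under 0.05), gave 0 to 351 and 0 to 520, the high values without such pairs. Lists called were 13 to 17 for A3, 11 to 13 for Tmem, 4 to 13 for ALL1, 10 to 15 for ALL1_A3 and 5 to 9 for ALL1_Tmem. The share of the A3 response kept was 0.188 to 1.02, with no value without either A3 array since nothing was called, and that of the Tmem response 0.968 to 1.08. Shared A3 and Tmem calls were 0 to 1598. With only the groups of a comparison in the fit, A3 gave 29, ALL1 0 (1534 at unadjusted p under 0.05), ALL1_A3 1 and ALL1_Tmem 3. Such fits have fewer arrays to estimate the spread. Those with untreated or ALL1_A3 also take it from replicates that lay farther apart than in the other groups. Array weights gave 165 for A3, 51 for ALL1_A3, 113 for ALL1_Tmem and 1 for the interaction with Tmem. A 2-fold threshold, stricter by construction, left 119, 1458, 20, 39, 8 and 948. With 1 probe set per gene, where fewer are tested, Tmem gave 3958 and Tmem against A3 2697. A filter at 6 gave 127 for ALL1. A trended, robust prior gave 162 for ALL1, 278 for ALL1_A3, 2 for the interaction with A3 and 10 for that with Tmem. With an estimated correlation camera called 0 lists in all 5 comparisons, and fry 1 for ALL1, 2 for ALL1_A3 and 0 for ALL1_Tmem. After quantile normalization the share of the Tmem response kept was 1.03. The labels do not say what a replicate number marks. Deviations of equally numbered arrays correlated positively in all 15 group pairs (0.0497 to 0.709), a hint of shared handling, but above 0.1 in 11 of them and not in all, so the numbers were not taken as pairs. With the replicate number as a block, A3 gave 768, ALL1 189, ALL1_A3 386, ALL1_Tmem 51, the interaction with Tmem 2, shared calls 622 and the share of the Tmem response kept 1.04. Of the named genes, none reversed under any setting that was run. In the 12 fits without 1 array, 44 of 48 calls for Tmem and 44 of 46 for Tmem against A3 passed every time, but 0 of 40 for A3, 0 of 14 for ALL1, 0 of 23 for ALL1_A3 and 0 of 11 for ALL1_Tmem, all with the same sign. Except where a construction is named, the cause was not tested. Genes at or below 4 have bounds only, as signal near the floor limits their precision.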

Other observations

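The mean effect of the peptide over the 3 backgrounds and the test of a hypothesis in this part were chosen after the data had been seen.

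Averaged over untreated, A3-activated and membrane-activated cells, the peptide changed 740 probe sets in limma, 328 higher and 412 lower, in 437 genes. Of these, 295 and 384 had the same direction in all 3 backgrounds. Calls on the mean favour equal directions by construction, and the share expected from this was not computed. The untreated and A3-activated backgrounds also hold the untreated and ALL1_A3 arrays, for which an exchange of labels stays open. MSMO1 rose by a mean of 0.90 log2 units (adjusted p = 0.00391), with 1.22 in untreated, 1.11 in A3-activated and 0.38 in membrane-activated cells. HMGCS1 rose by 0.80 (0.90, 1.05 and 0.45), LMO2 by 0.66, KIF21B by 0.65, and the plasminogen activator genes PLAU and PLAT by 0.62 and 0.57. Both arrays with the peptide lay above both without it for 20, 21 and 15 of the 23 sterol synthesis genes in untreated, A3-activated and membrane-activated cells, or 87.0%, 91.3% and 65.2%, and below for 0, 0 and 2. Over all genes 20.9%, 25.2% and 18.9% were higher in this way and 21.2%, 16.6% and 31.7% lower, where chance gives 16.7% in each direction. That chance is for a gene taken alone. Genes of a list can shift together between arrays, so these counts are not a test of the list. With an estimated correlation, camera gave the sterol list an adjusted p of 0.391, 0.166 and 0.687 in the 3 backgrounds. SPP1, the osteopontin gene, fell by 2.01 (adjusted p = 0.0127), with changes of -2.72, -2.09 and -1.23. HEY1 fell by 1.61 (-2.59, -1.70 and -0.53), IL24 fell by 1.49 (-1.78, -2.19 and -0.50) and NR4A3 fell by 1.45 (-1.75, -2.37 and -0.24), while HMOX1 fell by 1.04 (-0.57, -0.85 and -1.70). The count of 740 was 1317 without untreated replicate 2 and 1167 without ALL1_A3 replicate 1. It was 487 without untreated replicate 1, 328 and 232 without ALL1 replicates 1 and 2, 332 and 477 without A3 replicates 1 and 2, 384 without ALL1_A3 replicate 2, 264 and 338 without Tmem replicates 1 and 2, and 276 and 275 without ALL1_Tmem replicates 1 and 2.

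HMOX1, TXNRD1 and GCLM, which fell with the peptide in membrane-activated cells, are targets of the antioxidant transcription factor NRF2. A hypothesis is that NRF2 targets as a set were lower there, and a list of other targets was written from general knowledge after those falls were seen. Both ALL1_Tmem arrays lay below both Tmem arrays for 14 of the 21 other measured targets, or 66.7%, and above for 3. Of all genes 31.7% were lower in this way, and chance gives 16.7% for a gene taken alone. Targets can shift together between arrays, so the count is not a test of the set. None of the 21 passed limma, and their median difference was -0.11, so the set may be lower by a small amount. The same count was 12 of 21 (57.1%, with 21.2% of all genes) in untreated cells and 7 of 21 (33.3%, with 16.6%) in A3-activated cells. In Tmem against untreated, 11 of the 21 were lower in this way (52.4%, with 46.6% of all genes) and 6 higher, with a median of -0.15. The other targets as a set were thus not raised by membranes, but members moved both ways. SLC7A11, ME1 and OSGIN1 passed limma as higher, by 3.35, 0.95 and 0.39, as HMOX1, TXNRD1 and GCLM had. TKT, PGD, GSR, PRDX1 and TALDO1 passed as lower, with changes of -0.50, -0.36, -0.29, -0.26 and -0.23. OSGIN1 differed by -0.72, -0.57 and -0.64 in untreated, A3-activated and membrane-activated cells, and GCLC by -0.52 with membranes. Other causes of these differences were not tested.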
